A study of Jaculus jaculus and Mus musculus with 24 samples.

How the data were processed

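Total RNA of hindfoot muscle and forelimb FDS muscle from jerboa and mouse at P0 and P3 was measured by high throughput sequencing in 24 libraries, 3 for each of 8 groups. The deposited files hold raw read counts, whole numbers with no normalization, for 17641 features named by mouse Ensembl transcript identifiers in both species. The authors' processing notes name STAR, with no version. The genome builds, annotations, trimming settings and library protocol are not given in the sources used here. Per the labels, the read files were trimmed for P0 and original for P3, so age coincides with that difference. Each file has 3 count columns, for reads of either strand, of one strand and of the opposite strand. Between 98.4% and 99.6% of the reads assigned to a strand fell in the last column, which was used as the count.

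Symbols, chromosomes and positions came from the mouse GENCODE M21 annotation (GRCm38), which may differ from the annotation the authors used. It paired 17529 features with a symbol, left 112 without one, and gave 5 symbols to more than 1 feature. No mitochondrially encoded feature was present. Totals ran from 16.7 M to 54.7 M reads per library. A count of 0 allows up to 3 reads, which is a level of 0.0549 to 0.179 CPM in 1 library. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Where a group had 0 reads, the fold is a bound against 3 reads over the group, and where it had 1 to 3 reads the ratio is given with its counting interval (95%).

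Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood F test), with 1 coefficient for each of the 8 groups. That left 14448 genes and 16 residual degrees of freedom, with a common biological coefficient of variation of 0.0842. The p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. There were 12 comparisons, namely foot against forelimb in each species and age, the difference of these effects between species at each age and between ages in each species, the difference of those differences, age in jerboa foot, and species in foot at each age. Adjusted counts within 41 gene and marker lists were also taken over each list alone. Lists were tested with camera (preset correlation 0.01, limma 3.58.1) in 7 comparisons, with 1 adjustment over the 287 tests, and with a correlation estimated per list. Comparisons, lists, the rule for named genes and the alternatives, except those given below as added, were fixed before the data were examined.

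Named genes were the 5 largest increases and 5 largest decreases with an adjusted p under 0.05, a mean of at least 10 CPM in 1 group and, in comparisons of 2 groups, no overlap between libraries. To these were added up to 4 members with the smallest p in each list described, and 19 genes of muscle growth, atrophy, synapse and limb identity chosen beforehand. In the change with age in jerboa the last part was left out. A few named genes are not reported here. Counts were simulated with known changes in 50 genes per fold and with 14208 of 14448 genes unchanged. On these, the test of jerboa foot against forelimb recovered 34.0% of 1.25-fold, 66.0% of 1.5-fold, 80.0% of 2-fold and 84.0% of 4-fold changes. Of its calls 3.55% were false. The real comparison called 9527 genes at P0, far more than were changed in the simulation, so these rates need not carry over to the data. The test of a difference between species recovered 0%, 50.0%, 66.0% and 84.0%, with 4.76% false calls, and 0 of 40 unchanged sets were called by camera. The alternatives tried were DESeq2 size factors (RLE) and upper quartile scaling, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma voom, only the libraries compared, a block for the replicate number, a minimum of 2-fold, and each library left out in turn. Reads of either strand, a filter on both species and, for the list tests, the other scalings were added after seeing the data. Library numbers were not used as pairs in the main test. Gene levels were not compared between species gene by gene, because lengths and models of genes differ between the genomes.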

Results

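RNA from the muscle inside the hindfoot and from the flexor digitorum superficialis (FDS) of the forelimb was sequenced in the lesser Egyptian jerboa (Jaculus jaculus), a bipedal rodent, and in the laboratory mouse. Each species was sampled at birth (P0) and at postnatal day 3 (P3), which gave 8 groups of 3 libraries and 24 libraries in all. The jerboa loses its hindfoot muscle as it grows and keeps the forelimb muscle, whereas the mouse keeps both. The series asks which genes differ in the muscle that is lost. Foot muscle came from sections and forelimb muscle from dissection, in both species, so the way of sampling differed between the tissues throughout. Totals of reads are given as group means. In jerboa the group means were 18.1 ± 1.19 M reads in foot at P0 and 28.5 ± 6.74 in foot at P3, against 31.8 ± 4.34 and 31.5 ± 2.17 in forelimb (SD, n = 3). In mouse they were 27.4 ± 3.84 and 41.6 ± 8.26 M in foot, against 41.0 ± 4.47 and 49.9 ± 4.23 in forelimb. Levels are given in CPM, read counts scaled by normalised library size (mean ± SD, n = 3), and changes as log2 fold changes of foot over forelimb ± SE. The labels do not say whether the libraries of a group came from separate animals, so each p measures the spread between these libraries.

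Tbx4 and Tbx5 differed between the limbs in both species. Tbx4, a T-box gene of the developing hindlimb, was at 118 ± 11.7 CPM in jerboa foot and 4.34 ± 0.823 CPM in jerboa forelimb at P0, and at 60.3 ± 3.70 CPM and 17.0 ± 0.579 CPM in mouse. Tbx5, its forelimb counterpart, was at 0.602 ± 0.729 CPM in jerboa foot and 9.11 ± 0.711 CPM in jerboa forelimb at P0, and at 0.0762 ± 0.0400 CPM and 13.3 ± 1.91 CPM in mouse. Other genes of the list of forelimb identity did not follow Tbx5. Of its 5 measured members, Tbx5 and 4 Hoxc genes, 3 were higher and 1 lower in jerboa foot at P0, and 4 were higher and 1 lower in each of the other 3 comparisons of foot and forelimb, with the same counts adjusted over the list alone. Camera called this list in none of the 4 (adjusted p from 0.39 to 0.93). Libraries of a group resembled one another across genes (r from 0.987 to 0.997 over 24 pairs of libraries, where genes are not independent replicates).

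Foot and forelimb muscle were first compared in newborn mice, which keep both. The genes furthest up in the foot (3 libraries per group) were Hoxc10 (8.20 ± 0.33) and Hoxc11 (7.12 ± 0.32), homeobox genes of the hindlimb, then Spp1 (4.16 ± 0.36), a secreted phosphoprotein of bone matrix, Chad (3.98 ± 0.18), a matrix protein of cartilage and tendon, and Crabp2 (3.27 ± 0.12), which carries retinoic acid. The genes furthest down were Tbx5 (-7.39 ± 0.42), Aqp4 (-6.83 ± 0.30), the water channel of fast fibres, Pvalb (-6.47 ± 0.32), a calcium buffer of fast fibres, Mybpc2 (-5.23 ± 0.19), the fast myosin binding protein C, and Plin4 (-5.03 ± 0.22), a lipid droplet protein. Perinatal myosin Myh8 (-2.17 ± 0.14), muscle creatine kinase Ckm (-1.65 ± 0.10), skeletal actin Acta1 (-1.06 ± 0.12) and the neuronal nitric oxide synthase Nos1 (-1.38 ± 0.12) were also lower in foot. Myog, the myogenic regulator of differentiation (1.12 ± 0.09), and Fgf6, a growth factor made by muscle (1.06 ± 0.16), were higher, and Hgf, a growth factor that activates satellite cells, was lower (-2.45 ± 0.27). The ubiquitin ligase gene Fbxo32 was lower (-0.86 ± 0.14) and its partner in atrophy Trim63 was not called (-0.28 ± 0.13, adjusted p = 0.062). Trim63 was called with limma voom (-0.31, adjusted p = 0.040), and at -0.49 without replicate 1 of mouse foot at P0 (adjusted p = 0.0012) and -0.38 without replicate 2 of mouse forelimb at P0 (adjusted p = 0.024).

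The contractile and metabolic genes were lower in mouse foot as groups. Of 48 measured sarcomere genes, 36 were lower, 6 higher and 6 not called (36 and 6 adjusted over the list alone), with Myoz3 at -4.58 ± 0.20 and Tnnc1, of slow fibres, at 1.31 ± 0.07. Their median was -0.76 (camera adjusted p = 1.3e-08, adjusted p = 0.37 with an estimated correlation). Genes of excitation-contraction coupling were lower in 21 of 24 cases, higher in 0 and not called in 3 (22 and 1 adjusted over the list alone), with the calcium release channel Ryr1 at -1.76 ± 0.07. The median was -0.89, and camera gave an adjusted p of 1.4e-13 (adjusted p = 0.033 with an estimated correlation). Among the 21 measured genes of glycolysis and creatine phosphate, 20 were lower and 0 higher (20 and 0 adjusted over the list alone), and 1 was not called, with Ckmt2 at -4.46 ± 0.18. At -1.18, the list median came with a camera adjusted p of 6.5e-24 (adjusted p = 0.029 with an estimated correlation). Genes of oxidative phosphorylation numbered 38, of which 36 were lower, 0 higher and 2 not called (36 and 0 adjusted over the list alone), with Cox7a1 at -2.41 ± 0.16. A median of -0.76 had a camera adjusted p of 1.3e-12 (adjusted p = 0.35 with an estimated correlation). Of 24 measured genes of the dystrophin complex, 16 were lower, 3 higher and 5 not called (16 and 3 adjusted over the list alone), with Dmd at -1.43 ± 0.07. Their median was -0.65 (camera adjusted p = 3.1e-06, adjusted p = 0.061 with an estimated correlation). Genes of nitric oxide signalling were lower in 17 of 30 cases, higher in 4 and not called in 9 (17 and 4 adjusted over the list alone). The adjusted p by camera was 0.0030 (adjusted p = 0.033 with an estimated correlation). Among the 34 measured cell cycle genes, 25 were higher and 1 lower (26 and 1 adjusted over the list alone), and 8 were not called, with Aurkb at 0.72 ± 0.09. At 0.44, the list median came with a camera adjusted p of 9.0e-04 (adjusted p = 0.62 with an estimated correlation). Genes of the endoplasmic reticulum stress response numbered 27, of which 16 were higher, 2 lower and 9 not called (16 and 2 adjusted over the list alone), with Ppp1r15a at 0.79 ± 0.09. A median of 0.34 had a camera adjusted p of 0.036 (adjusted p = 0.35 with an estimated correlation).

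Markers of other cell types moved beside these groups. Of 12 measured tendon markers, 11 were higher, 0 lower and 1 not called (11 and 0 adjusted over the list alone), with Scx at 1.10 ± 0.13. Their median was 0.84 (camera adjusted p = 3.0e-04, adjusted p = 0.31 with an estimated correlation). Endothelial markers were lower in 8 of 10 cases, higher in 1 and not called in 1 (9 and 1 adjusted over the list alone), with Tek at -1.10 ± 0.07. The median was -0.65, and camera gave an adjusted p of 1.2e-04 (adjusted p = 0.32 with an estimated correlation). Among the 12 measured markers of smooth muscle and pericytes, 7 were lower and 3 higher (8 and 3 adjusted over the list alone), and 2 were not called. At -0.63, the list median came with a camera adjusted p of 0.033 (adjusted p = 0.26 with an estimated correlation). Markers of fibro-adipogenic cells numbered 12, of which 9 were lower, 2 higher and 1 not called (9 and 2 adjusted over the list alone), with Ly6a at -2.46 ± 0.13. A median of -0.91 had a camera adjusted p of 4.4e-04 (adjusted p = 0.31 with an estimated correlation). Of 10 measured fat cell markers, 4 were lower, 1 higher and 5 not called (4 and 1 adjusted over the list alone). Camera gave 0.019 as their adjusted p (adjusted p = 0.26 with an estimated correlation). Macrophage markers were lower in 5 of 15 cases, higher in 2 and not called in 8 (4 and 2 adjusted over the list alone). The median was -0.01, and the list was not called (adjusted p = 0.91). Among the 20 measured neuromuscular junction genes, 10 were higher and 9 lower (10 and 9 adjusted over the list alone), and 1 was not called. At a median of 0.12, camera made no call (adjusted p = 0.72). Cartilage (9 of 15) and bone markers (5 of 7) were higher, 0 lower, with no call by camera (adjusted p = 0.077 and 0.054). In the edgeR test 8527 of 14448 genes were called, 4299 higher and 4228 lower in foot.

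In mice at P3, Hoxc10 (9.55 ± 0.35) and the autopod homeobox genes Hoxd12 (4.26 ± 0.20) and Hoxd13 (3.77 ± 0.12) were higher in foot (3 libraries per group), with Sct, the secretin gene (3.73 ± 0.16), and Lars2, a mitochondrial tRNA synthetase gene (4.18 ± 0.59) whose level differed widely between libraries of mouse forelimb at P0. Tbx5 had 0 reads in foot and 1579 in forelimb, at least 477-fold lower against a floor of 3 reads over the group. Aqp4 (-7.47 ± 0.20), the tubulin gene Tuba8 (-5.92 ± 0.24), Mybpc2 (-5.06 ± 0.17) and Pvalb (-4.85 ± 0.24) were lower. Nos1 (-1.75 ± 0.12), Hgf (-0.81 ± 0.24), Ckm (-0.87 ± 0.10) and Acta1 (-0.96 ± 0.12) were lower in foot, and Trim63 was slightly lower (-0.37 ± 0.13). Embryonic myosin Myh3 (1.51 ± 0.11), Myog (1.39 ± 0.09) and the fetal acetylcholine receptor subunit Chrng (1.47 ± 0.12) were higher. The P3 change of Trim63 was -0.33 without replicate 1 of mouse foot at P3 (adjusted p = 0.060) and -0.30 without replicate 1 of mouse forelimb at P3 (adjusted p = 0.078).

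Contractile and energy genes were lower in the P3 mouse foot too. Sarcomere genes numbered 48, of which 35 were lower, 9 higher and 4 not called (35 and 9 adjusted over the list alone), with the embryonic light chain Myl4 at 1.97 ± 0.09 and Myoz3 at -2.97 ± 0.15. A median of -0.58 had a camera adjusted p of 0.0021 (adjusted p = 0.70 with an estimated correlation). Of 24 measured genes of excitation-contraction coupling, 18 were lower, 0 higher and 6 not called (20 and 1 adjusted over the list alone). Their median was -0.54 (camera adjusted p = 1.1e-08, adjusted p = 0.11 with an estimated correlation). Genes of glycolysis and creatine phosphate were lower in 19 of 21 cases, higher in 0 and not called in 2 (19 and 0 adjusted over the list alone). The median was -0.78, and camera gave an adjusted p of 4.9e-13 (adjusted p = 0.13 with an estimated correlation). Among the 38 measured genes of oxidative phosphorylation, 36 were lower and 0 higher (37 and 0 adjusted over the list alone), and 2 were not called. At -0.66, the list median came with a camera adjusted p of 7.1e-14 (adjusted p = 0.35 with an estimated correlation). Genes of nitric oxide signalling numbered 30, of which 15 were lower, 5 higher and 10 not called (15 and 5 adjusted over the list alone), with the arginine transporter Slc7a2 at -1.21 ± 0.09. The list had a camera adjusted p of 0.0071 (adjusted p = 0.044 with an estimated correlation). Of 24 measured genes of the dystrophin complex, 16 were lower, 3 higher and 5 not called (16 and 3 adjusted over the list alone). Their median was -0.34 (camera adjusted p = 1.2e-04, adjusted p = 0.16 with an estimated correlation). Cell cycle genes were higher in 32 of 34 cases, lower in 1 and not called in 1 (32 and 1 adjusted over the list alone). The median was 0.48, and camera gave an adjusted p of 6.8e-06 (adjusted p = 0.45 with an estimated correlation). Among the 38 measured extracellular matrix genes, 20 were higher and 6 lower (21 and 6 adjusted over the list alone), and 12 were not called. At 0.25, the list median came with a camera adjusted p of 0.011 (adjusted p = 0.71 with an estimated correlation). Myogenic regulators numbered 35, of which 18 were higher, 8 lower and 9 not called (18 and 8 adjusted over the list alone), with the fusion genes Mymx at 1.96 ± 0.12 and Mymk at 1.08 ± 0.07. Camera did not call the list (adjusted p = 0.051).

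Of 12 measured tendon markers, 12 were higher, 0 lower and 0 not called (12 and 0 adjusted over the list alone). Their median was 1.03 (camera adjusted p = 5.1e-07, adjusted p = 0.10 with an estimated correlation). Cartilage markers were higher in 13 of 15 cases, lower in 0 and not called in 2 (13 and 0 adjusted over the list alone), with Cnmd at 5.14 ± 0.41. The adjusted p by camera was 5.0e-05 (adjusted p = 0.080 with an estimated correlation). Among the 10 measured endothelial markers, 10 were lower and 0 higher (10 and 0 adjusted over the list alone), and 0 were not called, with Flt1 at -1.54 ± 0.09. At -1.05, the list median came with a camera adjusted p of 5.5e-14 (adjusted p = 0.029 with an estimated correlation). Markers of smooth muscle and pericytes numbered 12, of which 10 were lower, 1 higher and 1 not called (11 and 1 adjusted over the list alone), with Myh11 at -3.06 ± 0.29. A median of -0.63 had a camera adjusted p of 3.0e-04 (adjusted p = 0.039 with an estimated correlation). Of 10 measured fat cell markers, 9 were lower, 1 higher and 0 not called (9 and 1 adjusted over the list alone), with Adipoq at -6.19 ± 0.56. Camera gave 1.7e-06 as their adjusted p (adjusted p = 0.029 with an estimated correlation). Markers of fibro-adipogenic cells were lower in 8 of 12 cases, higher in 1 and not called in 3 (8 and 1 adjusted over the list alone). The median was -0.77, and camera gave an adjusted p of 0.0016 (adjusted p = 0.35 with an estimated correlation). The test called 7591 genes, 3941 higher and 3650 lower. The effects at P0 and P3 in mouse correlated across genes at r = 0.592, and 4936 of 5400 genes called at both ages had the same direction.

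In newborn jerboas the comparison sets the muscle that will be lost against one that stays. Hoxc10 (6.59 ± 0.30), Hoxc11 (5.63 ± 0.29) and the hindlimb gene Pitx1 (5.92 ± 0.31) were higher in foot (3 libraries per group), together with Stmn4, a regulator of microtubules best known from neurons (6.03 ± 0.40), and Corin, a serine protease of the cell surface (5.07 ± 0.19). The largest decreases were in Mettl11b, a methyltransferase gene (-5.76 ± 0.30), the phosphatase gene Dupd1 (-4.19 ± 0.18), the chloride channel gene Clic5 (-4.09 ± 0.36), the mitochondrial uncoupling protein gene Ucp3 (-4.04 ± 0.32) and the slow myosin light chain gene Myl2 (-3.87 ± 0.32). Nos1 (mouse GRCm38, chromosome 5, 117841850 to 117958840) had 0 reads in the 3 foot libraries and 123 in the forelimb, at least 23.7-fold lower against a floor of 3 reads over the group. Ass1, which recycles citrulline to arginine, the substrate of nitric oxide synthases (chromosome 2, 31470207 to 31520672), was at 1689.5 ± 77.5 CPM in foot and 66.4 ± 14.7 CPM in forelimb (4.67 ± 0.13).

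Among the genes followed in each comparison, Myh8 (-2.76 ± 0.14), Ckm (-2.26 ± 0.10) and Acta1 (-1.04 ± 0.12) fell in the jerboa foot at P0. Fgf6 (-1.76 ± 0.21, chromosome 6, 127015586 to 127028187), its receptor gene Fgfr4 (-0.61 ± 0.10), the HGF receptor gene Met (-1.20 ± 0.11) and the satellite cell gene Pax7 (-1.004 ± 0.12) were lower, while Hgf was not called (-0.21 ± 0.26, adjusted p = 0.50). Of the genes of the neuromuscular synapse, Chrng (1.36 ± 0.12), the kinase gene Musk (0.98 ± 0.07) and the receptor subunit gene Chrna1 (0.33 ± 0.07) were higher. The list went both ways, with 9 of 20 higher, 8 lower and 3 not called (9 and 8 adjusted over the list alone), and was not called (adjusted p = 0.79). Myog was higher (0.63 ± 0.09). Of the ubiquitin ligase genes of muscle atrophy, Trim63 was higher (0.66 ± 0.13, 104 ± 19.5 CPM against 65.8 ± 4.18 CPM) and Fbxo32 was not called (-0.17 ± 0.21, adjusted p = 0.49). Myh3 just missed the threshold (-0.24 ± 0.11, adjusted p = 0.052). Myh3 was called with upper quartile scaling (-0.27, adjusted p = 0.031), with no filter on low counts (-0.25, adjusted p = 0.038) and with reads of either strand (-0.25, adjusted p = 0.045), and at -0.32 without replicate 3 of jerboa foot at P0 (adjusted p = 0.022) and -0.36 without replicate 1 of jerboa forelimb at P0 (adjusted p = 0.0046).

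As in mouse, contractile and energy genes were lower in foot. Among the 48 measured sarcomere genes, 31 were lower and 10 higher (32 and 10 adjusted over the list alone), and 7 were not called, with Ldb3 at -1.04 ± 0.08 and the slow troponin gene Tnnt1 at 1.35 ± 0.10. At -0.52, the list median came with a camera adjusted p of 0.0058 (adjusted p = 0.75 with an estimated correlation). Genes of excitation-contraction coupling numbered 24, of which 16 were lower, 2 higher and 6 not called (16 and 2 adjusted over the list alone), with the sodium channel Scn4a at -1.82 ± 0.09. A median of -0.68 had a camera adjusted p of 1.2e-04 (adjusted p = 0.35 with an estimated correlation). Of 21 measured genes of glycolysis and creatine phosphate, 16 were lower, 3 higher and 2 not called (16 and 3 adjusted over the list alone). Their median was -0.98 (camera adjusted p = 7.3e-07, adjusted p = 0.35 with an estimated correlation). Genes of oxidative phosphorylation were lower in 31 of 38 cases, higher in 0 and not called in 7 (32 and 0 adjusted over the list alone). The median was -0.65, and camera gave an adjusted p of 1.5e-05 (adjusted p = 0.63 with an estimated correlation). Among the 24 measured genes of the dystrophin complex, 15 were lower and 6 higher (15 and 6 adjusted over the list alone), and 3 were not called. At -0.53, the list median came with a camera adjusted p of 0.041 (adjusted p = 0.51 with an estimated correlation). Extracellular matrix genes numbered 38, of which 25 were higher, 6 lower and 7 not called (25 and 7 adjusted over the list alone), with Tgfb3 at 1.67 ± 0.10 and Bgn at 1.09 ± 0.07. A median of 0.47 had a camera adjusted p of 0.0015 (adjusted p = 0.62 with an estimated correlation). Of 42 measured genes of denervation and atrophy, 16 were higher, 13 lower and 13 not called (16 and 14 adjusted over the list alone), with the receptor subunit Chrnd at 1.43 ± 0.09. Their median was 0.15, with no call by camera (adjusted p = 0.46). Apoptosis genes were higher in 14 of 39 cases, lower in 13 and not called in 12 (14 and 13 adjusted over the list alone). The list was not called (adjusted p = 0.92).

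Markers of other cells differed between the jerboa muscles, beside the groups above. Among the 10 measured endothelial markers, 10 were lower and 0 higher (10 and 0 adjusted over the list alone), and 0 were not called, with Cdh5 at -2.06 ± 0.09 and Kdr at -1.73 ± 0.07. At -1.81, the list median came with a camera adjusted p of 5.2e-13 (adjusted p = 0.035 with an estimated correlation). Markers of smooth muscle and pericytes numbered 12, of which 8 were lower, 3 higher and 1 not called (8 and 3 adjusted over the list alone). A median of -0.97 had a camera adjusted p of 0.0052 (adjusted p = 0.12 with an estimated correlation). Of 15 measured macrophage markers, 14 were lower, 1 higher and 0 not called (14 and 1 adjusted over the list alone), with Mrc1 at -1.94 ± 0.12 and Cd68 at 1.21 ± 0.11. Their median was -0.96 (camera adjusted p = 0.0044, adjusted p = 0.45 with an estimated correlation). Fat cell markers were lower in 5 of 10 cases, higher in 1 and not called in 4 (5 and 1 adjusted over the list alone). The adjusted p by camera was 0.010 (adjusted p = 0.23 with an estimated correlation). Among the 12 measured tendon markers, 11 were higher and 0 lower (11 and 0 adjusted over the list alone), and 1 was not called, with Comp at 3.29 ± 0.20. At 1.31, the list median came with a camera adjusted p of 5.6e-05 (adjusted p = 0.23 with an estimated correlation). Cartilage markers numbered 15, of which 9 were higher, 1 lower and 5 not called (9 and 1 adjusted over the list alone). A median of 1.05 went without a call (adjusted p = 0.055). Of 12 measured keratinocyte markers, 6 were higher, 0 lower and 6 not called (6 and 0 adjusted over the list alone). Their median was 0.96, with no call by camera (adjusted p = 0.076). Immediate early genes were higher in 12 of 22 cases, lower in 0 and not called in 10 (12 and 0 adjusted over the list alone). The median was 0.63, and the list was not called (adjusted p = 0.15). Among the 13 measured Schwann cell markers, 9 were lower and 1 higher (9 and 1 adjusted over the list alone), and 3 were not called, with Cnp at -0.87 ± 0.10. At a median of -0.81, camera made no call (adjusted p = 0.39). The edgeR test called 9527 of 14448 genes, 4501 higher and 5026 lower in foot.

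In the jerboa foot at P3, Corin (6.39 ± 0.20), Ass1 (5.61 ± 0.14) and the mast cell chymase gene Cma1 (5.39 ± 0.33) were among the 5 furthest up (3 libraries per group). The other two, Hoxc10 and Hoxc11, had 1 and 3 reads in forelimb, for ratios of 2238 (counting interval 401 to 88447) and 386 (132 to 1873). Mettl11b (-6.28 ± 0.26), Mybpc2 (-6.08 ± 0.31), Aqp4 (-5.77 ± 0.31), Myl2 (-5.04 ± 0.34) and Dupd1 (-4.68 ± 0.18) were furthest down. Ass1 was at 2902 ± 309 CPM in foot and 59.6 ± 8.59 CPM in forelimb. Nos1 was lower (-3.51 ± 0.30, 0.225 ± 0.0270 CPM against 2.57 ± 0.211 CPM).

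Myh8 (-3.37 ± 0.14), Fgf6 (-2.73 ± 0.23), Ckm (-2.17 ± 0.10), Acta1 (-1.40 ± 0.12), Pax7 (-1.34 ± 0.12), Met (-1.33 ± 0.10), Hgf (-0.91 ± 0.23) and Fgfr4 (-0.87 ± 0.10) were all lower in the jerboa foot at P3. Trim63 was higher (1.18 ± 0.13), at 131 ± 6.75 CPM against 57.7 ± 1.02 CPM, as were Chrng (1.60 ± 0.12), Myog (0.70 ± 0.09) and Musk (0.43 ± 0.07).

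Sarcomere genes were lower in the jerboa foot at P3. Sarcomere genes numbered 48, of which 35 were lower, 8 higher and 5 not called (35 and 8 adjusted over the list alone), with Ldb3 at -1.23 ± 0.08. A median of -0.82 had a camera adjusted p of 1.0e-05 (adjusted p = 0.53 with an estimated correlation). Of 24 measured genes of excitation-contraction coupling, 18 were lower, 2 higher and 4 not called (18 and 2 adjusted over the list alone), with sarcolipin, Sln, at -2.24 ± 0.14. Their median was -0.48 (camera adjusted p = 1.3e-04, adjusted p = 0.35 with an estimated correlation). Genes of glycolysis and creatine phosphate were lower in 16 of 21 cases, higher in 2 and not called in 3 (16 and 2 adjusted over the list alone), with Ak1 at -1.71 ± 0.09. The median was -0.75, and camera gave an adjusted p of 5.0e-07 (adjusted p = 0.35 with an estimated correlation). Among the 38 measured genes of oxidative phosphorylation, 29 were lower and 1 higher (30 and 1 adjusted over the list alone), and 8 were not called, with Cox8b at -2.23 ± 0.14. At -0.55, the list median came with a camera adjusted p of 1.3e-04 (adjusted p = 0.70 with an estimated correlation). Genes of the dystrophin complex numbered 24, of which 15 were lower, 5 higher and 4 not called (15 and 5 adjusted over the list alone), with Dtna at -1.48 ± 0.08. A median of -0.41 had a camera adjusted p of 0.0014 (adjusted p = 0.26 with an estimated correlation). Of 32 measured proteasome subunit genes, 28 were higher, 1 lower and 3 not called (28 and 1 adjusted over the list alone), with Psmb2 at 0.81 ± 0.07 and Psmc4 at 0.67 ± 0.08. Their median was 0.40 (camera adjusted p = 0.0043, adjusted p = 0.76 with an estimated correlation). Genes of HGF signalling were lower in 17 of 25 cases, higher in 4 and not called in 4 (18 and 4 adjusted over the list alone), with Plau, a protease that activates HGF, at -2.20 ± 0.12 and Ets1 at -1.88 ± 0.10. The median was -0.59, and camera gave an adjusted p of 0.026 (adjusted p = 0.17 with an estimated correlation). Among the 38 measured extracellular matrix genes, 26 were higher and 9 lower (26 and 10 adjusted over the list alone), and 3 were not called, with periostin, Postn, at 1.72 ± 0.11. At 0.48, the list median came with a camera adjusted p of 0.0063 (adjusted p = 0.69 with an estimated correlation). Apoptosis genes numbered 39, of which 17 were higher, 9 lower and 13 not called (17 and 9 adjusted over the list alone). Camera did not call the list (adjusted p = 0.76). Of 42 measured genes of denervation and atrophy, 16 were higher, 15 lower and 11 not called (16 and 15 adjusted over the list alone). Their median was -0.02, with no call by camera (adjusted p = 0.86).

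Markers of vessels were lower beside these groups. Endothelial markers were lower in 10 of 10 cases, higher in 0 and not called in 0 (10 and 0 adjusted over the list alone), with Cdh5 at -2.72 ± 0.09 and Pecam1 at -2.26 ± 0.10. The median was -2.26, and camera gave an adjusted p of 9.5e-19 (adjusted p = 0.012 with an estimated correlation). Among the 12 measured markers of smooth muscle and pericytes, 9 were lower and 3 higher (9 and 3 adjusted over the list alone), and 0 were not called, with Abcc9 at -2.15 ± 0.09. At -1.26, the list median came with a camera adjusted p of 4.1e-04 (adjusted p = 0.044 with an estimated correlation). Fat cell markers numbered 10, of which 5 were lower, 1 higher and 4 not called (5 and 1 adjusted over the list alone), with leptin, Lep, at -2.72 ± 0.11. The list had a camera adjusted p of 0.0066 (adjusted p = 0.18 with an estimated correlation). Of 12 measured tendon markers, 11 were higher, 0 lower and 1 not called (12 and 0 adjusted over the list alone), with Tnmd at 1.80 ± 0.15. Their median was 1.36 (camera adjusted p = 5.0e-05, adjusted p = 0.23 with an estimated correlation). Macrophage markers were lower in 9 of 15 cases, higher in 1 and not called in 5 (9 and 1 adjusted over the list alone). The median was -0.34, and the list was not called (adjusted p = 0.45). Among the 13 measured Schwann cell markers, 11 were lower and 1 higher (11 and 1 adjusted over the list alone), and 1 was not called, with the myelin gene Mbp at -3.80 ± 0.48. At a median of -1.57, camera made no call (adjusted p = 0.11). The test called 9817 genes, 5183 higher and 4634 lower. The jerboa effects at P0 and P3 correlated across genes at r = 0.741, and 7260 of 7644 genes called at both ages had the same direction.

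**Figure D1:**
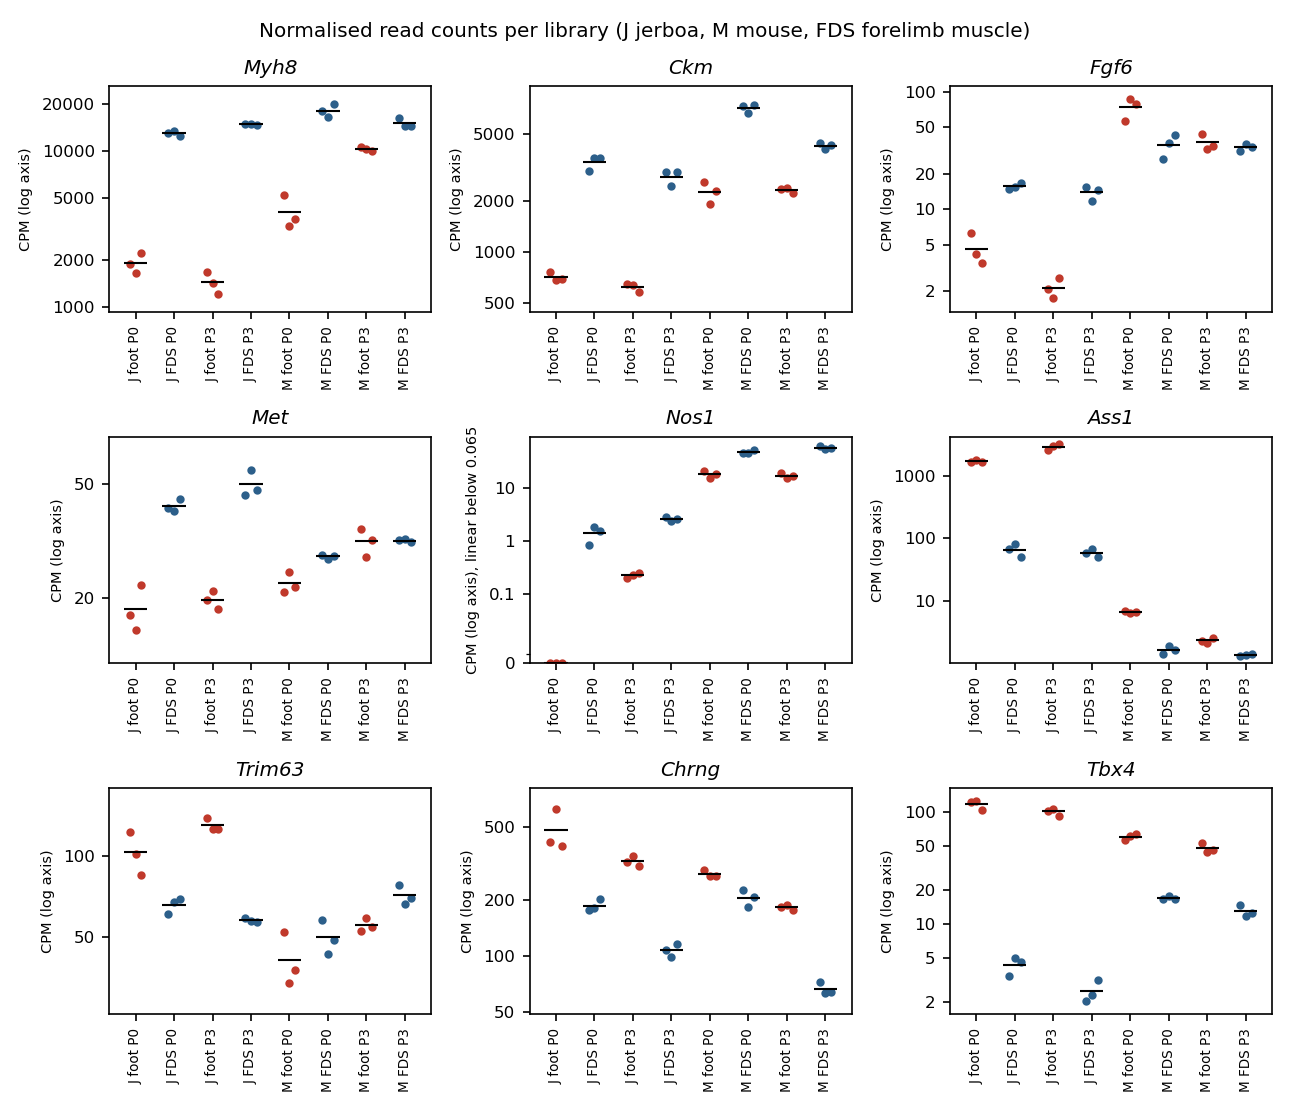
Normalised read counts in CPM (vertical log axes, each panel on its own scale) of 9 genes in the 8 groups, 1 point per library and a bar at the mean of 3, foot in red and forelimb (FDS) in blue. Ass1 lies at 1689.5 CPM (P0) and 2902 CPM (P3) on average in jerboa foot, and Nos1 has 0 reads in jerboa foot at P0.

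Whether the foot differs from the forelimb in another way in jerboa than in mouse was tested as the difference between the 2 species' effects. Properties of a gene's model in either genome cancel there only where they scale the counts of both tissues alike. Positive values mean a higher foot to forelimb ratio in jerboa (12 libraries at each age). At P0 the difference was largest upward for Stmn4 (6.15 ± 0.51), Dsp, a desmosome gene (5.66 ± 0.44), and Pvalb (5.12 ± 0.62), and downward for F2rl1, a receptor of proteases (-4.39 ± 0.37). Chrna9 and Cxcl11 upward and Nos1, Vwde, Casp12 and Ldoc1 downward had at most 3 reads in at least 1 group, so their difference has no reliable size. The call of Casp12 was lost without any 1 of the 3 jerboa foot libraries, or without replicate 1 of jerboa forelimb.

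Fgf6 fell in the jerboa foot (-1.76 ± 0.21) and rose in the mouse foot (1.06 ± 0.16), a difference of -2.82 ± 0.27. Pax7 (-1.21 ± 0.16), Fgfr4 (-1.20 ± 0.13), Met (-0.89 ± 0.15), Ckm (-0.62 ± 0.14), Myh8 (-0.60 ± 0.19) and Myog (-0.50 ± 0.13) were lower in jerboa foot than the mouse effect would give. Hgf (2.24 ± 0.38, chromosome 5, 16553550 to 16620152), Trim63 (0.94 ± 0.18), Fbxo32 (0.69 ± 0.25), Musk (0.95 ± 0.10) and Chrng (0.93 ± 0.16) were higher. Limb patterning genes differed too, with Tbx5 at 3.50 ± 0.79, Tbx4 at 2.94 ± 0.16 and Pitx1 at 2.35 ± 0.47. Acta1 was not called (0.02 ± 0.17, adjusted p = 0.96), nor was Myh3 (-0.28 ± 0.15, adjusted p = 0.13). The synapse gene Chrna1 was not called either (-0.23 ± 0.10, adjusted p = 0.059), though it was lower with upper quartile scaling (-0.28, adjusted p = 0.019), with limma voom (-0.23, adjusted p = 0.047), and at -0.30 without replicate 2 of jerboa foot at P0 (adjusted p = 0.020), -0.28 without replicate 2 of mouse foot at P0 (adjusted p = 0.032), -0.26 without replicate 3 of mouse foot at P0 (adjusted p = 0.0497) and -0.26 without replicate 1 of mouse forelimb at P0 (adjusted p = 0.046). The list of neuromuscular junction genes went both ways, with 8 of 20 higher, 6 lower and 6 not called (8 and 7 adjusted over the list alone), and was not called (adjusted p = 0.93). Several of these differences rest on single libraries. That of Tbx5 was 1.76 without replicate 1 of jerboa foot at P0 (adjusted p = 0.092), and that of Myh8 -0.37 without replicate 1 of mouse foot at P0 (adjusted p = 0.044). Fbxo32 was at 0.61 without replicate 1 of jerboa foot at P0 (adjusted p = 0.083), 0.64 without replicate 2 of mouse foot at P0 (adjusted p = 0.052) and 0.53 without replicate 1 of mouse forelimb at P0 (adjusted p = 0.074), and at 0.68, adjusted p = 0.14 with limma voom. Myh3 was called at -0.40 without replicate 1 of jerboa forelimb at P0 (adjusted p = 0.024) and -0.38 without replicate 3 of mouse foot at P0 (adjusted p = 0.044).

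Of 42 measured genes of denervation and atrophy, 22 were higher, 6 lower and 14 not called (23 and 7 adjusted over the list alone). Chrnd was at 1.04 ± 0.12 and the ligase gene Fbxo31 at 0.95 ± 0.12. Other lists share 10 of the 42, so the list is not specific to atrophy. A median of 0.37 had a camera adjusted p of 0.020 (adjusted p = 0.43 with an estimated correlation). Of 41 measured genes of autophagy and the lysosome, 15 were higher, 4 lower and 22 not called (15 and 4 adjusted over the list alone), with Map1lc3a at 1.18 ± 0.08. Their median was 0.07 (camera adjusted p = 0.017, adjusted p = 0.45 with an estimated correlation). Genes of glycolysis and creatine phosphate were higher in 11 of 21 cases, lower in 2 and not called in 8 (11 and 2 adjusted over the list alone), with Ckmt2 at 2.57 ± 0.23. The median was 0.42, and camera gave an adjusted p of 8.1e-04 (adjusted p = 0.54 with an estimated correlation). Among the 24 measured genes of excitation-contraction coupling, 12 were higher and 4 lower (13 and 4 adjusted over the list alone), and 8 were not called, with Kcnj11 at 1.29 ± 0.14. At 0.27, the list median came with a camera adjusted p of 0.046 (adjusted p = 0.65 with an estimated correlation). Extracellular matrix genes numbered 38, of which 23 were higher, 3 lower and 12 not called (23 and 5 adjusted over the list alone), with decorin, Dcn, at 1.77 ± 0.15 and Col14a1 at 1.88 ± 0.15. A median of 0.53 had a camera adjusted p of 6.8e-06 (adjusted p = 0.45 with an estimated correlation). Of 48 measured sarcomere genes, 18 were higher, 12 lower and 18 not called (20 and 12 adjusted over the list alone). Their median was 0.06, with no call by camera (adjusted p = 0.11). Myogenic regulators were lower in 18 of 35 cases, higher in 6 and not called in 11 (18 and 6 adjusted over the list alone), with Cdon at -1.33 ± 0.10 and Boc at 1.52 ± 0.11. The list was not called (adjusted p = 0.093). Among the 37 measured genes of FGF signalling, 12 were lower and 8 higher (12 and 8 adjusted over the list alone), and 17 were not called. No call was made by camera (adjusted p = 0.89).

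Markers of other cells moved with these groups. Endothelial markers numbered 10, of which 10 were lower, 0 higher and 0 not called (10 and 0 adjusted over the list alone), with Tek at -1.42 ± 0.11. A median of -1.03 had a camera adjusted p of 4.5e-07 (adjusted p = 0.16 with an estimated correlation). Of 15 measured macrophage markers, 11 were lower, 0 higher and 4 not called (11 and 0 adjusted over the list alone), with Csf1r at -1.31 ± 0.15 and C1qa at -1.33 ± 0.16. Their median was -0.98 (camera adjusted p = 5.9e-04, adjusted p = 0.35 with an estimated correlation). Markers of fibro-adipogenic cells were higher in 6 of 12 cases, lower in 2 and not called in 4 (6 and 2 adjusted over the list alone), with Lum at 2.01 ± 0.22 and Mfap5 at -1.34 ± 0.20. The adjusted p by camera was 0.030 (adjusted p = 0.54 with an estimated correlation). Among the 12 measured tendon markers, 6 were higher and 0 lower (7 and 0 adjusted over the list alone), and 6 were not called. At a median of 0.47, camera made no call (adjusted p = 0.055). Schwann cell markers numbered 13, of which 9 were lower, 1 higher and 3 not called (10 and 1 adjusted over the list alone). A median of -1.02 went without a call (adjusted p = 0.064). The test called 7019 of 14448 genes, 3127 higher and 3892 lower. Of the 3127 higher, 1050 were higher in jerboa foot and not called in mouse, 583 not called in jerboa and lower in mouse foot, and 491 higher in jerboa and lower in mouse. Both species had 675 of them higher and 286 lower, and neither called 42. Of the 3892 lower, 1297 were lower in jerboa foot and not called in mouse, 701 not called in jerboa and higher in mouse foot, and 611 lower in jerboa and higher in mouse. Both species had 1037 of them lower and 196 higher, and neither called 50. Across genes the effects of the 2 species correlated at r = 0.333 (rho = 0.417), and 5049 of 6151 genes called in both had the same direction.

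At P3 the jerboa effect exceeded the mouse effect most for Tuba8 (6.79 ± 0.34), Gcg, the proglucagon gene (6.69 ± 0.61), Myh15, a myosin heavy chain gene (5.58 ± 0.41), and Corin (5.34 ± 0.25). It fell below most for Lars2 (-5.28 ± 0.81), Tecrl, a gene of heart and muscle (-5.05 ± 0.42), and the neuronal gene Dpysl5 (-4.54 ± 0.15). Lars2 moved mostly in mouse (4.18 ± 0.59), where it varied at P0. Myo7b upward and Atp13a5 and Snx32 downward had at most 3 reads in at least 1 group, and the call of Myo7b was lost without any 1 of the 3 mouse foot libraries, or without replicate 1 or 2 of mouse forelimb, and with only the libraries of the comparison. Fgf6 (-2.86 ± 0.28), Myh8 (-2.82 ± 0.19), Nos1 (-1.76 ± 0.36), Myh3 (-1.60 ± 0.15), Met (-1.32 ± 0.14), Ckm (-1.30 ± 0.14), Pax7 (-1.24 ± 0.16), Fgfr4 (-1.23 ± 0.14), Myog (-0.70 ± 0.13) and Acta1 (-0.44 ± 0.17) were lower in jerboa foot relative to the mouse effect. Trim63 (1.55 ± 0.18), Musk (0.40 ± 0.10) and Tbx4 (3.48 ± 0.17) were higher. Hgf (-0.10 ± 0.33, adjusted p = 0.84), Fbxo32 (0.30 ± 0.23, adjusted p = 0.30), Chrna1 (-0.12 ± 0.10, adjusted p = 0.35) and Chrng (0.13 ± 0.16, adjusted p = 0.56) were not called. Pitx1 was called (adjusted p = 5.1e-06) and Tbx5 was not (adjusted p = 0.23), both with at most 3 reads in at least 1 group. Genes of the neuromuscular junction went both ways, with 5 of 20 higher, 7 lower and 8 not called (5 and 7 adjusted over the list alone), and the list was not called (adjusted p = 0.58). The call of Acta1 was lost without any 1 of 6 libraries of P3. It was at -0.37 without jerboa foot replicate 3 (adjusted p = 0.085). Without jerboa forelimb replicate 1 or 3 it was at -0.35 (adjusted p = 0.10) or -0.37 (adjusted p = 0.086). Without mouse foot replicate 1 or 2 it was at -0.41 (adjusted p = 0.066) or -0.44 (adjusted p = 0.053). Without mouse forelimb replicate 2 it was at -0.39 (adjusted p = 0.080).

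As a list, sarcomere genes lay lower in jerboa relative to mouse. Of 48 measured sarcomere genes, 19 were lower, 8 higher and 21 not called (22 and 8 adjusted over the list alone), with the embryonic light chain Myl4 at -2.77 ± 0.13 and cardiac actin Actc1 at -2.22 ± 0.13. Their median was -0.30 (camera adjusted p = 0.011, adjusted p = 0.76 with an estimated correlation). Myogenic regulators were lower in 20 of 35 cases, higher in 5 and not called in 10 (20 and 5 adjusted over the list alone), with Rb1 at -1.30 ± 0.09 and Cdon at -1.10 ± 0.09. The adjusted p by camera was 0.0019 (adjusted p = 0.35 with an estimated correlation). Among the 32 measured proteasome subunit genes, 24 were higher and 0 lower (26 and 0 adjusted over the list alone), and 8 were not called, with Psmb7 at 0.65 ± 0.11 and Psmd8 at 0.56 ± 0.10. At 0.38, the list median came with a camera adjusted p of 7.3e-04 (adjusted p = 0.71 with an estimated correlation). Genes of autophagy and the lysosome numbered 41, of which 20 were higher, 4 lower and 17 not called (20 and 4 adjusted over the list alone), with Mcoln1 at 0.77 ± 0.11. A median of 0.25 had a camera adjusted p of 0.019 (adjusted p = 0.45 with an estimated correlation). Of 19 measured chaperone genes, 8 were higher, 2 lower and 9 not called (9 and 2 adjusted over the list alone), with the crystallin Cryab at 1.79 ± 0.16. Their median was 0.34 (camera adjusted p = 0.032, adjusted p = 0.45 with an estimated correlation). Genes of denervation and atrophy were lower in 9 of 42 cases, higher in 10 and not called in 23 (9 and 10 adjusted over the list alone). The median was 0.05, and the list was not called (adjusted p = 0.91). Among the 30 measured genes of nitric oxide signalling, 11 were lower and 8 higher (11 and 8 adjusted over the list alone), and 11 were not called, with myoglobin, Mb, at 4.63 ± 0.21 and Ass1 at 4.85 ± 0.24. No call was made by camera (adjusted p = 0.91).

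Endothelial markers numbered 10, of which 10 were lower, 0 higher and 0 not called (10 and 0 adjusted over the list alone), with Cdh5 at -1.74 ± 0.12. A median of -0.90 had a camera adjusted p of 9.6e-07 (adjusted p = 0.17 with an estimated correlation). Of 12 measured keratinocyte markers, 4 were higher, 0 lower and 8 not called (4 and 0 adjusted over the list alone), with Trp63 at 2.05 ± 0.20. Camera gave 0.029 as their adjusted p (adjusted p = 0.42 with an estimated correlation). Satellite cell markers were lower in 5 of 9 cases, higher in 1 and not called in 3 (5 and 1 adjusted over the list alone), with Vcam1 at 2.18 ± 0.16 and Cdh15 at -1.27 ± 0.11. The median was -0.78, and the list was not called (adjusted p = 0.21). Among the 15 measured macrophage markers, 6 were lower and 1 higher (6 and 1 adjusted over the list alone), and 8 were not called. At a median of -0.25, camera made no call (adjusted p = 0.45). Tendon markers numbered 12, of which 6 were higher, 1 lower and 5 not called (6 and 1 adjusted over the list alone). A median of 0.42 went without a call (adjusted p = 0.27). The test called 7081 genes, 3480 higher and 3601 lower. Of the 3480 higher, 1542 were higher in jerboa foot and not called in mouse, 498 not called in jerboa and lower in mouse foot, and 482 higher in jerboa and lower in mouse. Both species had 762 of them higher and 157 lower, and neither called 39. Of the 3601 lower, 1392 were lower in jerboa foot and not called in mouse, 483 not called in jerboa and higher in mouse foot, and 567 lower in jerboa and higher in mouse. Both species had 1004 of them lower and 113 higher, and neither called 42. The effects of the species correlated across genes at r = 0.341 (rho = 0.405), and 4585 of 5634 genes called in both had the same direction.

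**Figure D2:**
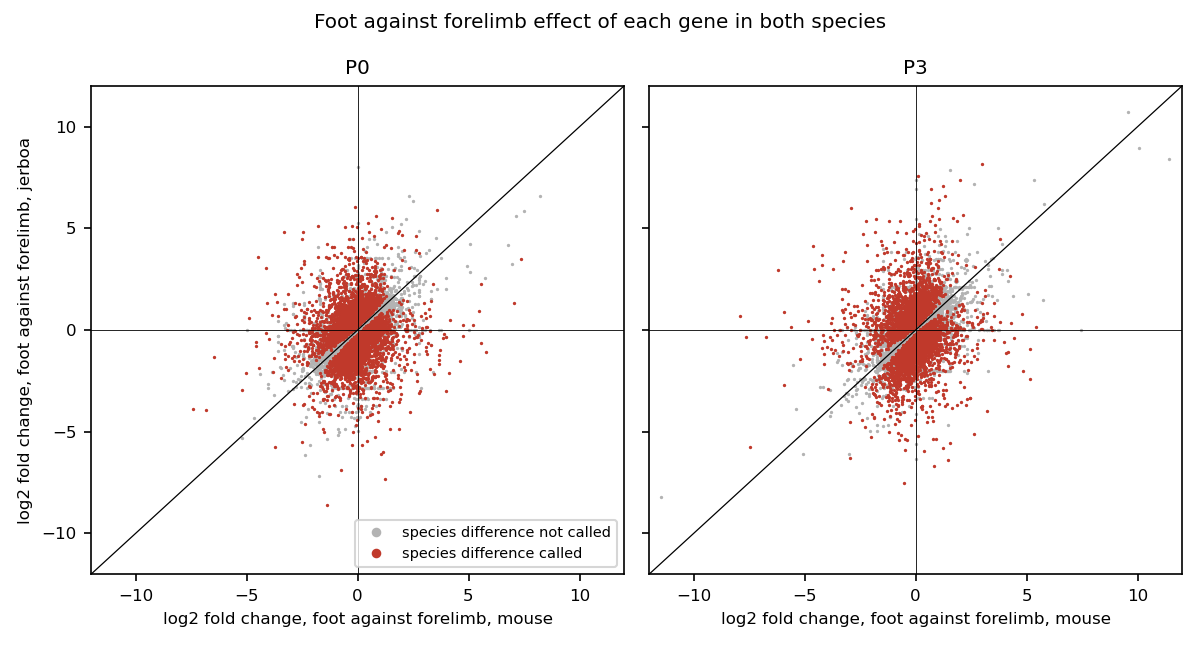
Each point is 1 of 14448 genes, with the log2 fold change of foot over forelimb in mouse on the horizontal axis and in jerboa on the vertical axis, at P0 and P3, and red where the difference between species was called. The 7019 red genes at P0 and 7081 at P3 lie away from the line of equal effects, on both sides of it.

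From P0 to P3 the foot to forelimb ratio changed in jerboa, measured as the effect at P3 minus that at P0. Clk1, a kinase of splicing factors (2.53 ± 0.33), the fructose transporter gene Slc2a5 (2.23 ± 0.54) and Rsrp1, a gene for a protein rich in arginine and serine (2.12 ± 0.18), had the largest rise of this ratio, next to Hoxc10 and Hoxc11, which had at most 3 reads in forelimb at P3. Their calls were lost without replicate 2 (Hoxc10) or 1 (Hoxc11) of forelimb at P0, and for Hoxc11 without replicate 3 of forelimb at P3. The myelin gene Mbp (-3.19 ± 1.04), Mybpc2 (-3.11 ± 0.998), Ankrd1, a gene induced by stretch (-2.71 ± 0.62), and Plin4 (-2.12 ± 0.42) were among those whose ratio fell most (12 libraries). A change in either tissue moves the ratio. From P0 to P3 Clk1 went from 203 ± 32.6 CPM to 331 ± 46.1 CPM in foot and from 234 ± 130.3 CPM to 66.2 ± 11.1 CPM in forelimb, and Mbp from 1.03 ± 0.743 CPM to 1.22 ± 1.06 CPM in foot and from 1.60 ± 0.363 CPM to 18.2 ± 12.5 CPM in forelimb. Mbp was at -2.40 without replicate 1 of jerboa foot at P0 (adjusted p = 0.24) and -2.89 without replicate 1 of jerboa foot at P3 (adjusted p = 0.051), and at -3.14, adjusted p = 0.077 with limma voom. The value of Mybpc2 was -2.35 without replicate 1 of jerboa foot at P0 (adjusted p = 0.25) and -3.11 without replicate 3 of jerboa foot at P0 (adjusted p = 0.061), and that of Ankrd1 -1.70 without replicate 3 of jerboa foot at P0 (adjusted p = 0.013).

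Higher and lower refer here to the ratio of foot to forelimb, which either tissue can move. Of 32 measured proteasome subunit genes, 15 were higher, 1 lower and 16 not called (16 and 1 adjusted over the list alone), with Psma6 at 1.19 ± 0.11. Their median was 0.34 (camera adjusted p = 3.3e-05, adjusted p = 0.62 with an estimated correlation). Genes of HGF signalling were lower in 10 of 25 cases, higher in 1 and not called in 14 (11 and 1 adjusted over the list alone), with Grb2 at -0.65 ± 0.09. The median was -0.34, and camera gave an adjusted p of 3.1e-05 (adjusted p = 0.012 with an estimated correlation). Among the 37 measured genes of FGF signalling, 13 were lower and 2 higher (13 and 2 adjusted over the list alone), and 22 were not called, with the feedback inhibitor Spry4 at -1.48 ± 0.21. For this list the camera adjusted p was 0.026, and adjusted p = 0.43 with an estimated correlation. Sarcomere genes numbered 48, of which 20 were lower, 7 higher and 21 not called (21 and 7 adjusted over the list alone), with Myl4 at -0.90 ± 0.12. A median of -0.27 had a camera adjusted p of 0.0016 (adjusted p = 0.70 with an estimated correlation). Of 22 measured immediate early genes, 5 were lower, 1 higher and 16 not called (5 and 1 adjusted over the list alone), with Klf4 at -1.18 ± 0.17. Their median was -0.42 (camera adjusted p = 0.034, adjusted p = 0.81 with an estimated correlation). Phagosome genes were higher in 16 of 53 cases, lower in 4 and not called in 33 (17 and 4 adjusted over the list alone), with Atp6v1a at 0.68 ± 0.10. The median was 0.29, and camera gave an adjusted p of 0.034 (adjusted p = 0.62 with an estimated correlation). Among the 15 measured macrophage markers, 7 were higher and 0 lower (11 and 0 adjusted over the list alone), and 8 were not called, with C1qa at 0.99 ± 0.16. At 0.67, the list median came with a camera adjusted p of 4.2e-04 (adjusted p = 0.35 with an estimated correlation). Markers of fibro-adipogenic cells numbered 12, of which 8 were lower, 0 higher and 4 not called (9 and 0 adjusted over the list alone), with Cd34 at -0.72 ± 0.10. The list had a camera adjusted p of 7.1e-05 (adjusted p = 0.23 with an estimated correlation). Of 10 measured endothelial markers, 5 were lower, 0 higher and 5 not called (7 and 0 adjusted over the list alone), with Emcn at -0.89 ± 0.21. Their median was -0.39 (camera adjusted p = 9.0e-04, adjusted p = 0.39 with an estimated correlation).

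The jerboa test called 4092 genes, 2343 higher and 1749 lower, so 57.3% were higher. With only the jerboa libraries in the fit the share was 45.9%, 1604 higher and 1893 lower, so the balance of directions rests on the libraries fitted. The same interaction in mouse called 4553 genes, and the difference between the species' interactions called 2971. In jerboa foot alone 6833 genes differed between P3 and P0, a comparison in which age coincides with read files that were trimmed at P0 and not at P3. Jerboa and mouse foot differed in 12284 genes at P0 and 12441 at P3. Those counts include differences between genomes and gene models, and no gene is named from them.

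**Figure D3:**
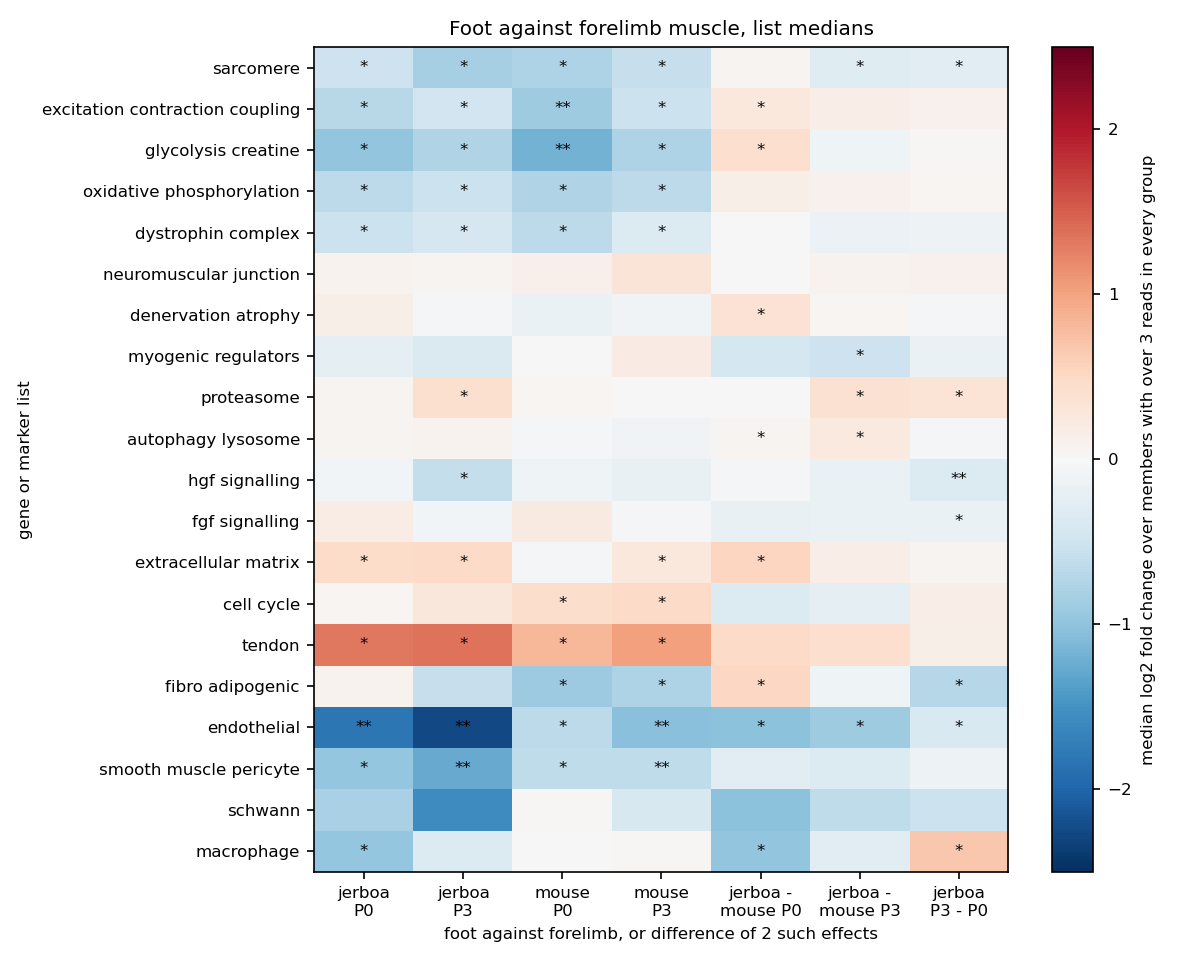
Median log2 fold change (color) of 20 gene or marker lists in the 4 comparisons of foot against forelimb, the 2 differences between species and the change with age in jerboa. Members with at most 3 reads in a group are left out of the medians. 1 star marks a camera call, and 2 stars a call that also holds with an estimated correlation, as for endothelium in jerboa at P0 and P3.

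Of 287 list tests, 83 were called with the preset correlation and 16 with an estimated one. Those 16 were the hindlimb identity list in the 4 comparisons of foot and forelimb, the endothelial list in all of these but mouse at P0, and the smooth muscle and pericyte list at P3 in both species. The others were nitric oxide signalling in mouse at both ages, excitation-contraction coupling and glycolysis in mouse at P0, the autopod identity and fat cell lists in mouse at P3, and HGF signalling in the jerboa interaction with age. The hindlimb identity list held 5 measured members, all higher in foot in each of the 4 comparisons (5 adjusted over the list alone), and its largest adjusted p with an estimated correlation was 0.012. It was called at P3 in the difference between species too, with 2 of 5 higher, 0 lower and 3 not called (2 and 0 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.40 with an estimated correlation). Of 6 measured autopod identity genes, 6 were higher in jerboa foot at both ages, and in mouse foot 5 were higher and 1 lower, with the same counts adjusted over the list alone. Camera called them in all 4 comparisons, with adjusted p = 0.078 (jerboa P0), 0.11 (jerboa P3), 0.18 (mouse P0) and 0.029 (mouse P3) with an estimated correlation.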

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

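The tests of endothelial markers, those of Nos1 and those of single libraries for Lars2 were chosen after their results were seen, whereas the test of Lars2 with reads of either strand and the counts over other splits of the libraries were written down beforehand. The breakdown of those splits by whether they kept a real tissue split was also chosen afterwards.

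Foot differed from forelimb in another way in jerboa than in mouse, by the test of the difference itself, in 7019 genes at P0 and 7081 at P3. The effect changed with age in 4092 genes in jerboa and 4553 in mouse, and that change differed between species in 2971. Of the genes followed throughout, the difference between species at P0 was called for Hgf (2.24 ± 0.38), Met (-0.89 ± 0.15), Fgf6 (-2.82 ± 0.27), Fgfr4 (-1.20 ± 0.13), Fbxo32 (0.69 ± 0.25), Trim63 (0.94 ± 0.18), Myog (-0.50 ± 0.13), Pax7 (-1.21 ± 0.16), Chrng (0.93 ± 0.16), Musk (0.95 ± 0.10), Myh8 (-0.60 ± 0.19), Ckm (-0.62 ± 0.14), Tbx4 (2.94 ± 0.16), Tbx5 (3.50 ± 0.79) and Pitx1 (2.35 ± 0.47). At P3 it was called for Met (-1.32 ± 0.14), Fgf6 (-2.86 ± 0.28), Fgfr4 (-1.23 ± 0.14), Nos1 (-1.76 ± 0.36), Trim63 (1.55 ± 0.18), Myog (-0.70 ± 0.13), Pax7 (-1.24 ± 0.16), Musk (0.40 ± 0.10), Myh3 (-1.60 ± 0.15), Myh8 (-2.82 ± 0.19), Acta1 (-0.44 ± 0.17), Ckm (-1.30 ± 0.14) and Tbx4 (3.48 ± 0.17). Nos1 at P0 (adjusted p = 2.0e-05) and Pitx1 at P3 (adjusted p = 5.1e-06) were called too, but had at most 3 reads in at least 1 group, so no size is given. Leaving out 1 library, as given above, could end the call of Tbx5 (1.76) or Fbxo32 (0.53 to 0.64) at P0. It could also end that of Acta1 at P3 (-0.44 to -0.35), and it moved Myh8 at P0 to -0.37. Reads of the strand not used made up 0.478% of strand-assigned reads in jerboa and 1.46% in mouse, a signal outside the main measurement.

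Splits of 3 against 3 libraries number 10, too few for a share under 0.05, and the real split stood alone (1 of 10) in each of the 7 such comparisons. In jerboa the real split of foot against forelimb called 9527 genes against at most 1 in the other splits at P0 and 9817 genes against at most 0 in the other splits at P3, and in mouse 8527 genes against at most 0 in the other splits at P0 and 7591 genes against at most 1 in the other splits at P3. For age in jerboa foot it called 6833 genes against at most 1 in the other splits, and for species in foot 12284 genes against at most 0 in the other splits at P0 and 12441 genes against at most 0 in the other splits at P3. For the differences of effects, 40 splits were drawn, out of 200 possible, or 80000 for the difference of differences. As many genes as in the real split were called in 1 of 40, real 7019, highest other 6926 for the difference between species at P0, and in 3 of 40, real 7081, highest other 7518 at P3. The same count was 5 of 40, real 4092, highest other 7479 for age in jerboa, 3 of 40, real 4553, highest other 5857 for age in mouse, and 1 of 40, real 2971, highest other 2685 for the difference of differences. This count does not test the differences of effects, and by it chance is neither excluded nor shown. A split that keeps the real split of foot from forelimb in a species or age turns that effect into a difference, and one that mixes the tissues puts it into the residual spread. In the order given, 6, 4, 5, 10 and 10 of the 39 other splits kept a real split, with at most 6926, 7518, 7479, 5857 and 2685 genes, and 0, 2, 4, 2 and 0 of them called as many genes as the real one. The 33, 35, 34, 29 and 29 splits that mixed the tissues throughout called at most 0, 0, 1, 0 and 1 genes.

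Endothelial markers fell further from forelimb to foot in jerboa than in mouse at P0, all 10 of them, with a median difference of -1.03 (adjusted p = 4.5e-07, and adjusted p = 0.16 with an estimated correlation). The list shares 0 members with other lists, and 10 of its 10 members reach 10 CPM in jerboa forelimb. A lower share of all tissue other than muscle would move tendon markers down as well, but their median was 0.47, which is 1.50 above that of the endothelial markers (SD of tendon members 0.961). Macrophage markers (median -0.98) and Schwann cell markers (median -1.02, list not called) were lower as well, so a lower share of vessels, macrophages and nerve together stays open and was not tested. RNA of an added tissue would lower muscle and vessel genes alike, but genes of excitation-contraction coupling lay 1.29 above the endothelial median, only just more than the SD of their members (1.27), at 0.27. Vessels may have been left out when the jerboa foot was sampled from sections, which cannot be told apart from fewer vessels in that muscle, because the way of sampling differed with the tissue.

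Lars2 was higher in mouse foot than forelimb at P3 (4.18 ± 0.59), at 1694 ± 484 CPM against 93.3 ± 11.3 CPM. The lowest foot library was 13.0 times the highest forelimb library. Within these groups the highest was at most 1.63 times the lowest. Lars2 was chosen for groups that do not overlap, so this gap tests no cause. Reads of either strand also gave 4.18 for Lars2, but the main count already leaves out the opposite strand, so nothing was tested. In mouse forelimb at P0 its level was 3882 ± 5255 CPM, and its highest library was 16.4 times the lowest, at percentile 99.9 of 1906 genes with at least 100 CPM. There a factor of single libraries may account for the spread. At P3 such a factor, a biological difference or one in sampling stays open and untested.

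Nos1 had 0 reads in jerboa foot at P0. At the rate of the forelimb, 71.1 reads would have been seen in the foot libraries, which argues against their lower depth. A lower share of muscle fibres would lower Nos1 with the sarcomere genes, but at P3 Nos1 lay -2.69 from their median of -0.82 (SD 1.32), although Mybpc2 (-6.08 ± 0.31) and Myl2 (-5.04 ± 0.34) fell further than Nos1 (-3.51 ± 0.30). An incomplete gene model would lower both jerboa tissues alike, and within jerboa the smallest change over 17 settings was -3.42 (largest adjusted p = 5.3e-07), while the gap in level to mouse stays open. A hypothesis that stays open is that Nos1 expression itself may be lower in the jerboa foot, as may be the share of the fibre types that carry it, which was not tested.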

How the results depend on the processing

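In each of the 12 comparisons the count of called genes stayed within 1.5 times of the count reported under 10 of 11 alternatives and with each library left out in turn. Over these settings the foot against forelimb counts were 8683 to 9633 (jerboa P0), 9220 to 9896 (jerboa P3), 7735 to 8746 (mouse P0) and 6668 to 9044 (mouse P3). The species by tissue interaction gave 6101 to 7191 at P0 and 6595 to 7966 at P3, and the tissue by age interaction 3416 to 4339 in jerboa and 3837 to 5013 in mouse. The exception was a minimum of 2-fold beside the adjusted p, which lowers a count by its construction. It left 3135, 3078, 1706 and 1490 genes for foot against forelimb in jerboa P0, jerboa P3, mouse P0 and mouse P3, 2207 and 2345 for the species by tissue interaction at P0 and P3, and 555, 835 and 909 for the tissue by age interaction in jerboa, in mouse and between them. For P3 against P0 in jerboa foot it left 882, and for jerboa against mouse in foot 7391 at P0 and 7569 at P3.

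The list tests moved as well. Of 287 gene list tests, 83 were called with the preset correlation, 16 with an estimated correlation, which allows for genes that move together, and 179 with fry, which asks whether a list moved at all and not whether it moved more than other genes. The 16 were all among the 83, and fry shared 81 of them. RLE scaling called 83, upper quartile scaling 86 and reads of either strand 83. Among the described lists, RLE scaling ended the calls of the dystrophin complex in jerboa at P0 and of immediate early genes in the change with age. Upper quartile scaling, and reads of either strand, each ended that of excitation-contraction coupling in the species by tissue interaction at P0. Myogenic regulators in mouse at P3, not called above, were called under each of these 3 settings, and tendon markers in the species by tissue interaction at P0 under upper quartile scaling. The cause was not tested.

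Of 825 results for single genes, 825 kept direction and call under RLE scaling, 820 under upper quartile scaling, 821 with DESeq2, 819 with limma voom and 823 with reads of either strand. The minimum of 2-fold ended 232 calls. Leaving out 1 library at a time ended 74 calls and added 19, against 6819 results whose call stayed, and no gene called in either fit reversed. A group left with 2 libraries keeps the spread pooled over all groups.

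No pairing of foot with forelimb by library number was seen. With 3 libraries per group and no animals named in the labels, shared animals are not excluded. Foot and forelimb libraries of one number correlated, after group means were removed, at r from -0.0863 to 0.115 over 12 pairs, and 3 of the 12 matched best with their own number. A block for the replicate number gave 9463 genes for foot against forelimb in jerboa P0, 9717 in jerboa P3, 8440 in mouse P0 and 7520 in mouse P3, 6927 and 6995 for the species by tissue interaction at P0 and P3, and 3896 for the tissue by age interaction in jerboa. With the block 99 gene list tests were called, with all 83 among them, and 13 of the 184 list results followed here gained a call, such as Schwann cell markers in jerboa P3 and tendon markers in the species by tissue interaction at P0. With the block Myh3 in jerboa P0 (-0.23, adjusted p = 0.038) and Trim63 in mouse P0 (-0.29, adjusted p = 0.022) were also called, as was Chrna1 in the species by tissue interaction at P0 (-0.23, adjusted p = 0.036), and Myo7b in the species by tissue interaction at P3 was not.

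Depth limits the genes with few reads. Genes without reads in a group have bounds only, and a difference between species has no reliable size where a group has at most 3 reads.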

Other observations

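The values that follow are for jerboa foot against forelimb at P3, in lists not described above for this comparison, none of them called. Genes of inflammation and interferon were higher in 9 of 30 cases, lower in 8 and not called in 13 (9 and 8 adjusted over the list alone). The list was not called (adjusted p = 0.36). Among the 33 measured genes for the engulfment of dead cells, 14 were lower and 6 higher (14 and 6 adjusted over the list alone), and 13 were not called. At a median of -0.32, camera made no call (adjusted p = 0.12). Markers of neutrophils and mast cells numbered 8, of which 3 were higher, 2 lower and 3 not called (3 and 2 adjusted over the list alone). Camera did not call the list (adjusted p = 0.27). Of 15 measured cartilage markers, 8 were higher, 1 lower and 6 not called (8 and 1 adjusted over the list alone). Their median was 1.17, with no call by camera (adjusted p = 0.055).

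The nitric oxide list moved in different parts. Ass1 rose in jerboa foot while Nos1 and the soluble guanylate cyclase gene Gucy1b1 fell (-2.02 ± 0.10 at P3), and myoglobin, Mb, was higher (2.95 ± 0.15). In mouse foot at P3 Mb was lower (-1.69 ± 0.14). Genes of nitric oxide signalling were lower in 16 of 30 cases, higher in 12 and not called in 2 (16 and 12 adjusted over the list alone). The list was not called (adjusted p = 0.15).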
